A study of Mus musculus with 16 samples.

How the data were processed

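Total RNA was extracted with TRIzol from the trunk or caudal region of E11.5 embryos, and libraries were made with standard Illumina protocols, per the labels' protocols. Reads were processed with fastp (version not given), HISAT2 2.0.5 and featureCounts 1.5.0-p3 on build mm39, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies therefore could not be assigned with certainty. The deposited values were FPKM, fragments per kilobase of gene length scaled to a library total, in 1 table with 1 column per library, per the file headers. Coordinates are those of the deposited table, on mm39, counted from 1. The reference supplied for mouse was of another build, so its coordinates were not used.

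The authors' FPKM multiplied by gene length gave whole numbers of reads, after division by 1 step per library, for 100% of values within 0.01. Those reads were used to give depth, between 34883821 and 43444905 reads in listed genes per library. At this depth the spread between libraries, not counting error, set the precision of all but the lowest genes. The total behind each library's FPKM was 0.949 to 1.03 times the sum of its listed reads. After the data were examined, these totals were set against median-of-ratios factors of the whole reads over the 20163 genes above 0 in every library. The ratio, scaled to the geometric mean of the listed totals, lay between 0.9984 and 1.003 in all 16 libraries. The deposited FPKM thus carry a scaling close to a median-of-ratios factor, and a further scaling of that kind changed little. Whole reads of libraries within a group differed by more than sampling noise in each pair (chi-square per degree of freedom from 5.795 to 17.78), so no library was counted as a repeat of another.

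Libraries were grouped by genotype and region from their titles. The main test was limma on log2(FPKM + 0.5) with 4 group means, a trended prior variance and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. All 16 libraries shared 1 estimate of the spread. Genes with at least 0.5 FPKM in at least 4 libraries were tested, 17205 in all, of which 13365 were protein-coding. Fold changes are on the log2(FPKM + 0.5) scale and understate the change of low genes. The comparisons were Ednrb-/- against WT in each region, trunk against caudal in each genotype, and the interaction. Which embryo each region came from is not given in the sources used here, so regions were treated as separate samples.

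There were 29 gene lists, tested with limma camera at a preset correlation of 0.01 and adjusted within each comparison. With an estimated correlation 2 of 66 list calls held, both for Hox paralogs 10 to 13 between the regions. As another alternative, fry tested whether the genes of a list move, on balance, 1 way. These 29 lists, the main tests, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The tests of causes among the flagged results, with their own lists of stage, melanoblast and glia genes, were made for patterns seen in the main results. The rule took Ednrb, the 8 largest rises and falls among called genes with a group mean of at least 1 FPKM, the endothelin genes, and up to 4 members of each list by adjusted p. The text names a part of these genes, picked after their values were seen. Melanoblast and endothelin genes below the filter were compared with a two-sided exact permutation test over 70 assignments, whose smallest p is 0.029.

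The procedure was tested on simulated data with 200 changed genes among 16640, drawn from genes with a mean above 1 FPKM. Far larger shares were called in the real genotype comparisons (41.6% caudal and 25.1% trunk). The rates below therefore do not cover such broad changes or low genes. Changes of 1.5-fold were recovered for 86% of genes in the caudal genotype comparison, 89% in the trunk, 90% between regions in WT and 84% in Ednrb-/-. Changes of 2-fold were recovered for 93%, 94%, 94% and 98%. False calls made up 3.763%, 3.175%, 4.167% and 3.191% of calls.

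Alternatives were other pseudocounts (0.1 and 1), no filter and a filter at 1 FPKM, TPM, median-of-ratios and quantile scaling, fits of only the groups compared, replicate number as a block, array weights, voom on the whole reads, a 2-fold minimum, and each library left out in turn. In the TPM alternative 1 common factor kept the pseudocount at its size on the FPKM scale. Alternatives added after the data were examined were a sex term, the sum of listed reads as the total, genes of chromosomes X, Y and MT left out, and 3 libraries with Xist and Ddx3y both at 5 FPKM or more left out. Work was done in R 4.3.3 with limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.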

Results

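RNA was sequenced from the trunk region and the caudal region of E11.5 mouse embryos. The embryos either carried the normal endothelin receptor B gene (Ednrb+/+, called WT here) or lacked a working copy (Ednrb-/-). This receptor is needed by migrating melanoblasts, the precursors of pigment cells, and by the neural crest cells that form the enteric nervous system. Each of the 4 groups had 4 libraries, described as biological replicates, which gave 16 libraries. The deposited values were FPKM for 56748 genes. The reads in the listed genes, recovered from the FPKM and the gene lengths, ranged from 34883821 to 43444905 per library. Y-linked genes were low and Xist high in 2 WT trunk, 1 WT caudal and 1 Ednrb-/- trunk library, and in 0 Ednrb-/- caudal libraries. The series asks how the local surroundings of pigment cells bear on where pigmented spots form in mice without this receptor.

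Ednrb, on chromosome 14 from 104052061 to 104081838 on the minus strand (ENSMUSG00000022122, mm39, protein-coding), was low in all 8 Ednrb-/- libraries. Its mean was 38.7 ± 2.79 FPKM (SD, n = 4) in WT trunk and 30.6 ± 3.17 FPKM in WT caudal tissue. It was 3.98 ± 0.596 FPKM in Ednrb-/- trunk and 2.34 ± 0.847 FPKM in Ednrb-/- caudal tissue. The highest Ednrb-/- library stood at 4.801 FPKM and the lowest WT library at 26.23 FPKM. On the log2(FPKM + 0.5) scale Ednrb fell by 3.49 ± 0.16 (SE) in the caudal region (limma, Benjamini-Hochberg adjusted p = 9.4e-09). It fell by 3.13 ± 0.16 in the trunk (adjusted p = 4.6e-08). The part of the gene that was altered is not given in the sources used here, so the remaining reads cannot be assigned to it. The highest Ednrb value of each Ednrb-/- group was in replicate 3 (trunk 4.801 FPKM, caudal 3.442 FPKM). Both of these libraries also held Xist and Y-linked RNA together, and a link was not tested.

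The first principal component held 42.9% of the variance and placed WT trunk libraries between 27 and 33.97 and Ednrb-/- caudal libraries between -48.79 and -30.6. WT caudal and Ednrb-/- trunk libraries lay between them on that component. The second component, with 12.4% of the variance, set WT caudal libraries (20.39 to 20.92) apart from Ednrb-/- trunk libraries (-19.79 to -16.64).

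**Figure D1:**
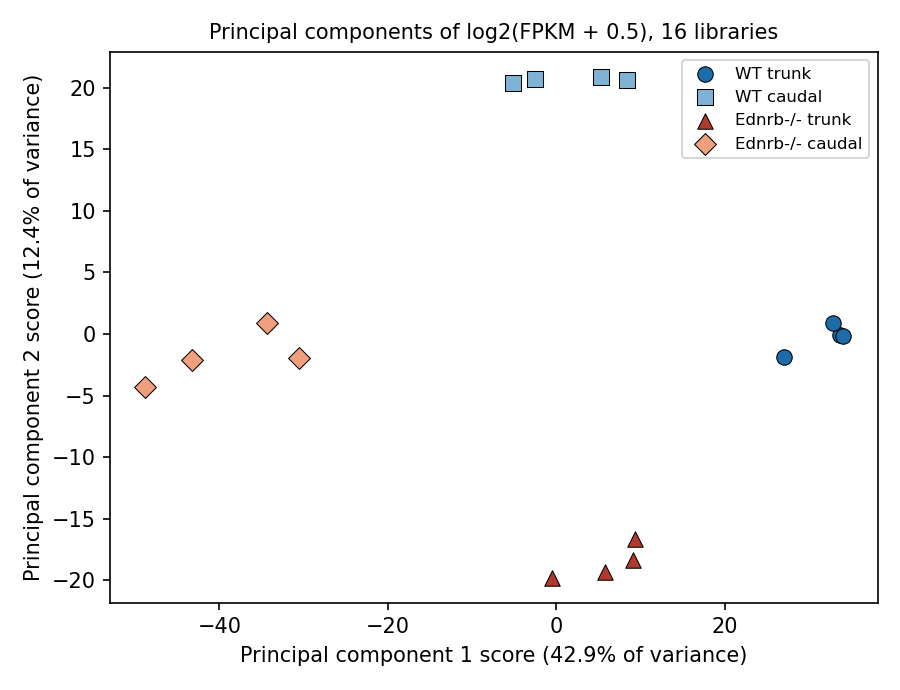
Scores of the 16 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 0.5), with 1 symbol per group of 4 libraries. The first component holds 42.9% of the variance and the second 12.4%, and no library lies among those of another group.

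The caudal regions of Ednrb-/- and WT embryos were compared to see what loss of the receptor changed in the posterior body. Melanoblast genes fell. Pmel, which builds the fibrils of the melanosome, went from 3.61 ± 0.171 to 0.594 ± 0.207 FPKM (SD, n = 4) and fell by 1.93 ± 0.13 on the log2 scale (limma adjusted p = 3.7e-07). Dct, a melanin synthesis enzyme, went from 1.63 ± 0.202 to 0.252 ± 0.106 FPKM and fell by 1.51 ± 0.15 (adjusted p = 6.2e-06). Gpnmb fell by 1.33 ± 0.12 (adjusted p = 3.3e-06) and Mitf, the transcription factor of the melanocyte lineage, by 0.51 ± 0.09 (adjusted p = 0.00042). Of the 8 melanoblast genes measured, 6 fell over all genes tested and 6 adjusted over the list alone. The list moved down (limma camera, adjusted p = 0.00012; adjusted p = 0.13 with an estimated correlation).

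Among the genes with the largest rises in caudal tissue was Lin28a, which blocks let-7 microRNA maturation and is high in early embryos. It rose from 3.6 ± 0.718 to 20.2 ± 8.96 FPKM (log2 2.26 ± 0.24, limma adjusted p = 9e-06). Arg1 rose by 2.05, Olig2 by 1.8, Gata5 by 1.61 and Wnt2 by 1.57. Tbx4, the T-box factor of the hindlimb, rose from 2.07 ± 1.51 to 8.77 ± 1.75 FPKM (2.03 ± 0.34, adjusted p = 0.00028). Igdcc3 rose by 1.53 ± 0.19 (adjusted p = 2.6e-05), and Snord43, a small nucleolar RNA, by 1.98. The largest falls after Ednrb were in Hbb-bs (-3.16), an adult beta globin, Mid1-ps1 (-3.01), Slc17a6 (-2.68), S100a9 (-2.33), Vstm2l (-2.31), Robo3 (-2.22) and Myod1 (-2.08). Their adjusted p-values ran from 3.7e-07 for Hbb-bs to 0.0037 for Mid1-ps1. Slc17a6, a vesicular glutamate transporter of neurons, went from 4.4 ± 1.03 to 0.279 ± 0.246 FPKM. Myod1, a regulator of skeletal muscle, went from 4.21 ± 1.03 to 0.623 ± 0.297 FPKM. Hbb-bs has a near-identical neighbour, Hbb-bt, which fell by 1.51, and reads shared between them could not be told apart here. Mid1-ps1 is a pseudogene on chromosome Y, and reads it may share with similar copies could not be assigned.

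Neural crest glia genes fell in caudal tissue for 13 of 15 measured members, and for 13 adjusted over the list alone (camera adjusted p = 4.7e-06; adjusted p = 0.13 with an estimated correlation). Fabp7 fell by 1.46, Cdh19 by 0.92, Erbb3 by 0.7 and Foxd3 by 0.7; 1 member of the list rose. Of 16 genes of autonomic and enteric neurons, 8 fell and 3 rose, 9 and 4 adjusted over the list alone, with Chgb at -1.5 and Gfra1 at -0.83 (adjusted p = 0.0086; adjusted p = 0.35 with an estimated correlation). Spinal neuron genes fell for 15 of 17 members, 15 adjusted over the list alone, among them Stmn2 (-1.54) and Lhx5 (-1.5) (adjusted p = 2.2e-08; adjusted p = 0.18 with an estimated correlation). Of 12 sensory neuron genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone, with Runx3 at -1.21 and Ntrk3 at -1.05 (adjusted p = 0.00025; adjusted p = 0.19 with an estimated correlation). Skeletal muscle genes fell for 11 of 14, 12 adjusted over the list alone, including Myh3 (-1.39) and Actc1 (-1.07) (adjusted p = 2.2e-08; adjusted p = 0.13 with an estimated correlation).

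Extracellular matrix genes fell for 18 of 28 members and rose for 4, 19 and 4 adjusted over the list alone, with Col6a3 at -1.8 and Col6a1 at -1.24 (camera adjusted p = 3.3e-05; adjusted p = 0.34 with an estimated correlation). Cartilage and sclerotome genes fell for 12 of 13, with 12 lower and 1 higher adjusted over the list alone, such as Pax1 (-0.67) and Sox6 (-0.47) (adjusted p = 6.9e-06; adjusted p = 0.16 with an estimated correlation). Macrophage genes fell for 11 of 13, 12 adjusted over the list alone, such as Csf1r (-0.66) and Mrc1 (-0.55) (adjusted p = 9e-05; adjusted p = 0.16 with an estimated correlation). Heart genes fell for 4 of 7 and rose for 1, the same counts adjusted over the list alone, with Myh7 at -1.02 (adjusted p = 0.04; adjusted p = 0.34 with an estimated correlation).

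Other lists rose in Ednrb-/- caudal tissue. Of 18 tailbud and presomitic genes 7 rose, 7 adjusted over the list alone, among them Cdx4 (1.38 ± 0.28), Cdx2 (1.22 ± 0.26) and Nkx1-2 (0.94 ± 0.13) (camera adjusted p = 0.0042; adjusted p = 0.49 with an estimated correlation). Foregut, lung and gut epithelium genes rose for 8 of 9, 8 adjusted over the list alone, such as Cldn6 (1.27) and Epcam (0.74) (adjusted p = 4.9e-05; adjusted p = 0.13 with an estimated correlation). Cell cycle genes rose for 18 of 20, and for 20 adjusted over the list alone, with Rrm2 at 0.54 and Mcm3 at 0.47 (adjusted p = 4.9e-09; adjusted p = 0.19 with an estimated correlation). Glycolysis and hypoxia genes rose for 13 of 20 and fell for 1, the same counts adjusted over the list alone, with Ldha at 0.9, Eno1 at 0.75 and Mif at 0.66 (adjusted p = 6.5e-06; adjusted p = 0.15 with an estimated correlation). Endothelial genes rose for 10 of 13, 11 adjusted over the list alone, such as Egfl7 (0.49) and Kdr (0.25) (adjusted p = 8.6e-05; adjusted p = 0.16 with an estimated correlation).

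The remaining 14 lists did not pass in this comparison. Hox paralogs 10 to 13, which pattern the posterior axis, rose for 2 and fell for 2 of 12, the same counts adjusted over the list alone (median -0.27, adjusted p = 0.5; adjusted p = 0.87 with an estimated correlation). Hoxd13 rose by 0.52 ± 0.12 (adjusted p = 0.003), a call lost with a pseudocount of 0.1 (adjusted p = 0.11), and Hoxc12 fell by 1.02 ± 0.13 (adjusted p = 2.8e-05). Adjusted p-values were 0.2 for Hox paralogs 1 to 8, 0.063 for erythroid, 0.87 for limb bud, 0.87 for liver and 0.94 for urogenital genes. They were 0.47 for surface ectoderm, 0.36 for neural progenitors, 0.086 for melanoblast guidance and survival, and 0.94 for the endothelin system. They were 0.87 for p53 targets, 0.43 for interferon response, 0.31 for dissociation stress and 0.94 for mitochondrially encoded genes. With an estimated correlation the adjusted p of these 13 lists was 0.39 or higher. Fry called the guidance and survival list (fry adjusted p = 0.0027) and the dissociation stress list (0.00016) as lower. In the erythroid list Hbb-bh1, an embryonic beta globin, rose by 0.82, while hemoglobin genes together took 0.33% ± 0.0857 (SD, n = 4) of reads against 0.429% ± 0.0388 in WT.

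The ligand side moved less. Edn3, the ligand of the receptor in the skin, went from 3.73 ± 0.339 to 2.95 ± 0.387 FPKM and fell by 0.29 ± 0.09 (limma adjusted p = 0.015). This call was lost after quantile normalization (adjusted p = 0.065) and without Ednrb-/- caudal replicate 2 (0.057) or WT caudal replicate 4 (0.056). Ece1, the enzyme that matures endothelins, rose by 0.33 ± 0.07 (adjusted p = 0.0023). Edn1 (0.33, adjusted p = 0.19) and Ednra (-0.19, adjusted p = 0.25) did not pass. Without Ednrb-/- caudal replicate 1 Edn1 had an adjusted p of 0.031, and without WT caudal replicate 3 Ednra had 0.035. Of 37 guidance and survival genes 16 fell and 7 rose, the same counts adjusted over the list alone, with Spon1 at -0.64 and Sema3c at -0.42 (camera adjusted p = 0.086; adjusted p = 0.39 with an estimated correlation). With fry this list was called as lower (fry adjusted p = 0.0027). Melanoblast genes too low for the model were tested exactly. Tyr, the first enzyme of melanin synthesis, stood at 0.00782 ± 0.0111 FPKM against 0.235 ± 0.0893 in WT, at the smallest p the exact permutation test of 4 against 4 can give (0.0286, two-sided, adjusted p = 0.0786). Slc45a2, Trpm1 and Mlph gave the same exact permutation p and adjusted p, so none passed after adjustment. With this smallest p, a gene can pass only if most of the low genes tested reach it. The failure to pass is therefore not evidence of no change.

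**Figure D2:**
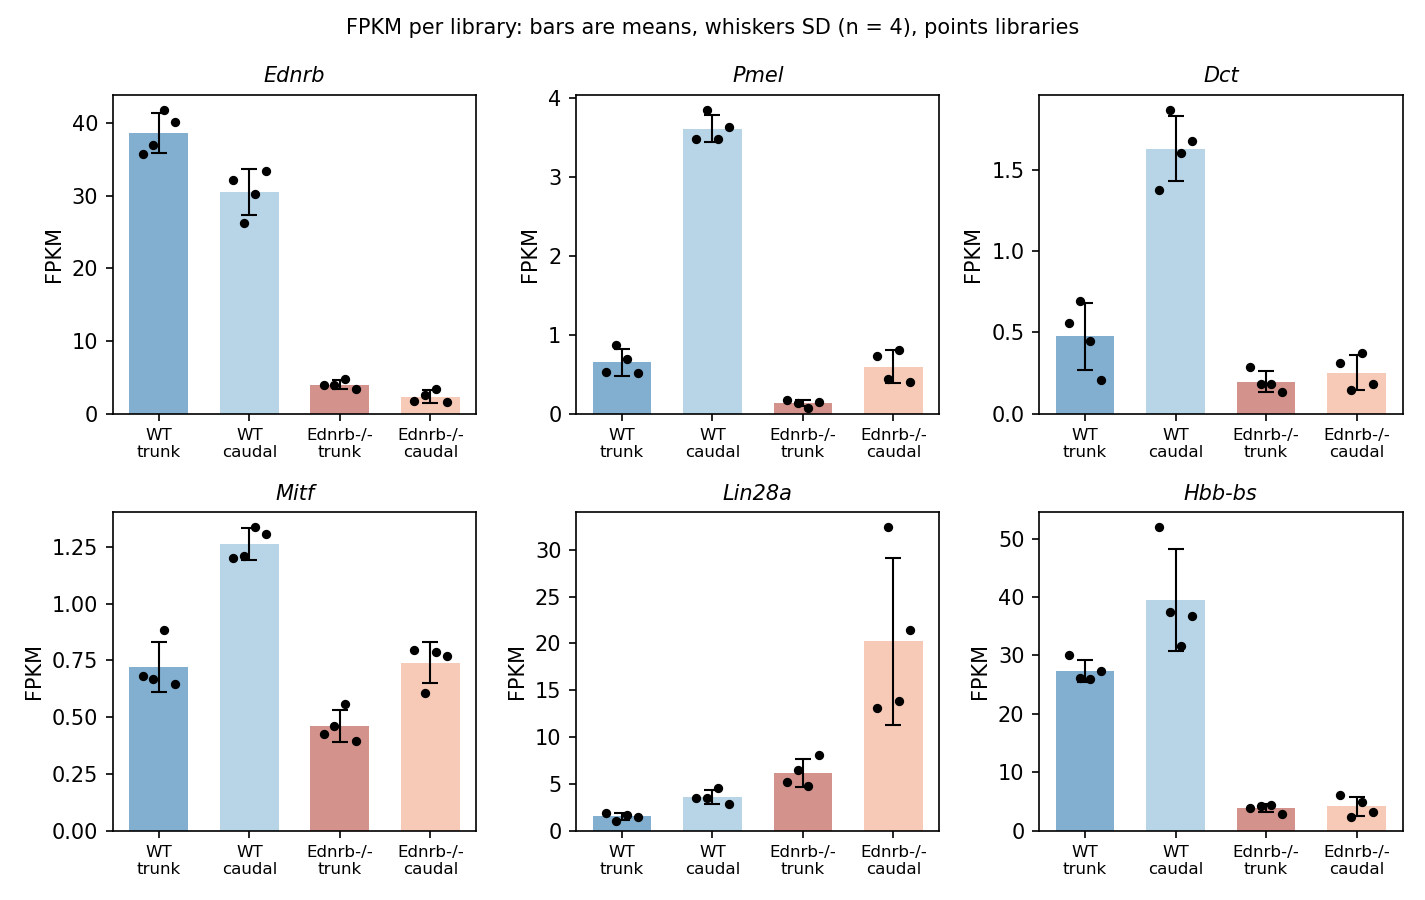
FPKM (y axes, starting at 0) of 6 genes in the 4 groups (x axes), where bars are means, whiskers are SD over 4 libraries and points are libraries. Ednrb reads stand at 4.801 FPKM or below in every Ednrb-/- library, Pmel and Dct are highest in WT caudal tissue, Lin28a averages 20.2 FPKM in Ednrb-/- caudal tissue, and Hbb-bs averages 3.82 and 4.13 FPKM in the Ednrb-/- groups.

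In all, 7164 of 17205 genes tested changed in caudal tissue (3732 rose and 3432 fell), of which 421 changed at least 2-fold (77 rose and 344 fell). The split of rises and falls depended on scaling. It was 2219 and 5017 after rescaling to TPM, 2613 and 4447 with voom on whole reads, and 2671 and 4352 with the sum of listed reads as the total. Library measures also differed between these groups: ribosomal protein genes took 3.68% ± 0.0825 of reads (SD, n = 4) against 3.07% ± 0.0893 in WT, mitochondrial genes 1.6% ± 0.0564 against 1.77% ± 0.101, and 13452 ± 117 against 13867 ± 85.5 genes reached 1 FPKM.

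In the trunk the same genotype comparison asked what loss of the receptor changed farther forward. Igdcc3 rose from 8.35 ± 1.01 to 34.9 ± 11.3 FPKM (SD, n = 4; log2 1.96 ± 0.19, limma adjusted p = 1.5e-05). Lin28a rose from 1.52 ± 0.361 to 6.15 ± 1.5 FPKM (1.71 ± 0.24, adjusted p = 0.00019), and Arg1 by 1.79. Hmx1, a homeobox factor, rose by 1.58, Atoh1, a factor of dorsal neuron progenitors, by 1.56, and Prtg by 1.43. The myogenic factors Myf6 and Myf5 rose by 1.53 and 1.26, Myf5 from 3.17 ± 0.213 to 8.28 ± 0.402 FPKM. Hbb-bs fell by 2.7 ± 0.21 (adjusted p = 3.3e-06), Mid1-ps1 by 2.75 ± 0.73 (0.012), and Ogn, a small proteoglycan, by 2.15 ± 0.16 (2.5e-06). Ogn went from 6.36 ± 1.11 to 1.06 ± 0.299 FPKM. Egfl6 fell by 2.02, Pirt by 1.91, Npy by 1.85, Matn4 by 1.81 and Hbb-bt by 1.56. Mir7655 stood at log2 1.44 (adjusted p = 0.041), a call lost with a pseudocount of 0.1 (0.067), without the filter (0.09) and with only the compared groups in the fit (0.095). It was also lost without any 1 of the 4 Ednrb-/- trunk libraries, or without WT trunk replicate 2 or 3 (adjusted p up to 0.096). The call of Mid1-ps1 was lost with voom (adjusted p = 0.057).

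Melanoblast genes were lower in the trunk too, from lower WT levels. Pmel went from 0.649 ± 0.169 to 0.132 ± 0.0419 FPKM and fell by 0.85 ± 0.13 (limma adjusted p = 0.00032). Mitf fell by 0.34 (adjusted p = 0.012), Gpnmb by 0.41 (0.022) and Dct by 0.47 (0.036). Dct went from 0.476 ± 0.206 to 0.196 ± 0.0638 FPKM. Of 8 members measured 4 fell, 4 adjusted over the list alone (camera adjusted p = 0.031; adjusted p = 0.42 with an estimated correlation). The list was not called without Ednrb-/- trunk replicate 4 (adjusted p = 0.078), WT trunk replicate 1 (0.051) or WT trunk replicate 2 (0.055). The call of Dct was lost without Ednrb-/- trunk replicate 2 (adjusted p = 0.073), 3 (0.068) or 4 (0.091), or WT trunk replicate 1 (0.085), 2 (0.12) or 3 (0.062), and that of Gpnmb without WT trunk replicate 2 (0.077) or with only the compared groups in the fit (0.064). That of Dct was also lost without the filter (0.072), with only the compared groups (0.078) and with array weights (0.078). Tyr, Slc45a2 and Mlph were again at the smallest exact permutation p (0.0286, adjusted p = 0.0786).

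Neural crest glia genes fell for 10 of 15 and rose for 1 in the trunk, 11 and 1 adjusted over the list alone, with Cdh19 at -0.84 (camera adjusted p = 3.5e-05; adjusted p = 0.2 with an estimated correlation). Extracellular matrix genes fell for 20 of 28 and rose for 2, the same counts adjusted over the list alone (adjusted p = 1.2e-08; adjusted p = 0.4 with an estimated correlation). Tnc fell by 1.34 and Thbs2 by 1.09, while Hapln1, which links hyaluronan to proteoglycans, rose by 1.01. Skeletal muscle genes fell for 10 of 14 and rose for 2, 10 and 3 adjusted over the list alone, with Myog at -0.76 and Actc1 at -0.63 (adjusted p = 0.0025; adjusted p = 0.53 with an estimated correlation). Macrophage genes fell for 7 of 13, 9 adjusted over the list alone, such as Mrc1 (-0.63) and C1qc (-0.53) (adjusted p = 0.00056; adjusted p = 0.4 with an estimated correlation). Erythroid genes fell for 7 of 14 and rose for 1, the same counts adjusted over the list alone (adjusted p = 0.01; adjusted p = 0.72 with an estimated correlation), and hemoglobin genes took 0.28% ± 0.0158 (SD, n = 4) of reads against 0.396% ± 0.0471 in WT. That call was lost without Ednrb-/- trunk replicate 1 (adjusted p = 0.05) or WT trunk replicate 1 (0.059).

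Cell cycle genes rose for 16 of 20 in the trunk, 19 adjusted over the list alone, such as Cenpe (0.27) and Mki67 (0.25) (camera adjusted p = 1.2e-08; adjusted p = 0.42 with an estimated correlation). Glycolysis and hypoxia genes rose for 13 of 20 and fell for 1, the same counts adjusted over the list alone, such as Eno1 (0.67) and Mif (0.62) (adjusted p = 2.8e-08; adjusted p = 0.2 with an estimated correlation). Hox paralogs 1 to 8 rose for 10 of 23, 11 adjusted over the list alone, led by Hoxb1 (1.01) and Hoxd1 (0.93) (adjusted p = 0.0019; adjusted p = 0.66 with an estimated correlation). Endothelial genes rose for 5 of 13, 7 adjusted over the list alone, such as Flt1 (0.41) and Plvap (0.41) (adjusted p = 0.012; adjusted p = 0.53 with an estimated correlation), a call lost without WT trunk replicate 3 (0.067). Neural progenitor genes rose for 3 of 13, 4 adjusted over the list alone, such as Neurog2 (0.49) and Pax6 (0.39) (adjusted p = 0.02; adjusted p = 0.7 with an estimated correlation). That list's call was lost with fry (adjusted p = 0.11) and without Ednrb-/- trunk replicate 4 (0.088) or WT trunk replicate 1 (0.16), and that of Pax6 without Ednrb-/- trunk replicate 4 (0.052). The other 18 lists did not pass in the trunk with camera. Fry called gut epithelium genes as higher (fry adjusted p = 0.027) and interferon response genes as lower (0.029).

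Edn3 fell by 0.39 ± 0.09 in the trunk (limma adjusted p = 0.0052), from 4.31 ± 0.47 to 3.16 ± 0.224 FPKM, and Ece1 rose by 0.29 ± 0.07 (adjusted p = 0.011). Edn1 (0.3, adjusted p = 0.29) and Ednra (0.03, adjusted p = 0.88) did not pass. Of 37 guidance and survival genes 7 fell and 5 rose, 9 and 9 adjusted over the list alone (camera adjusted p = 0.6; adjusted p = 0.86 with an estimated correlation). Cxcl12, a chemokine of migrating cells, rose by 0.41 and the guidance receptor Robo2 fell by 0.9. In all, 4321 genes changed in the trunk (2092 rose and 2229 fell), of which 187 changed at least 2-fold. The split was 1729 and 2965 with voom and 1643 and 2726 with the sum of listed reads as the total.

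The genotype effects in the regions, which share no library, were compared gene by gene. Across the 17205 genes the fold changes correlated (Pearson r = 0.58, Spearman rho = 0.55), where genes are not independent replicates. The lists shared 1396 rises, against 454 for independent lists, and 1595 falls, against 445, while 64 genes moved in opposite directions. Each gene's spread was estimated once over all libraries, which links its calls in both comparisons. The counts for independent lists may therefore be too low.

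**Figure D3:**
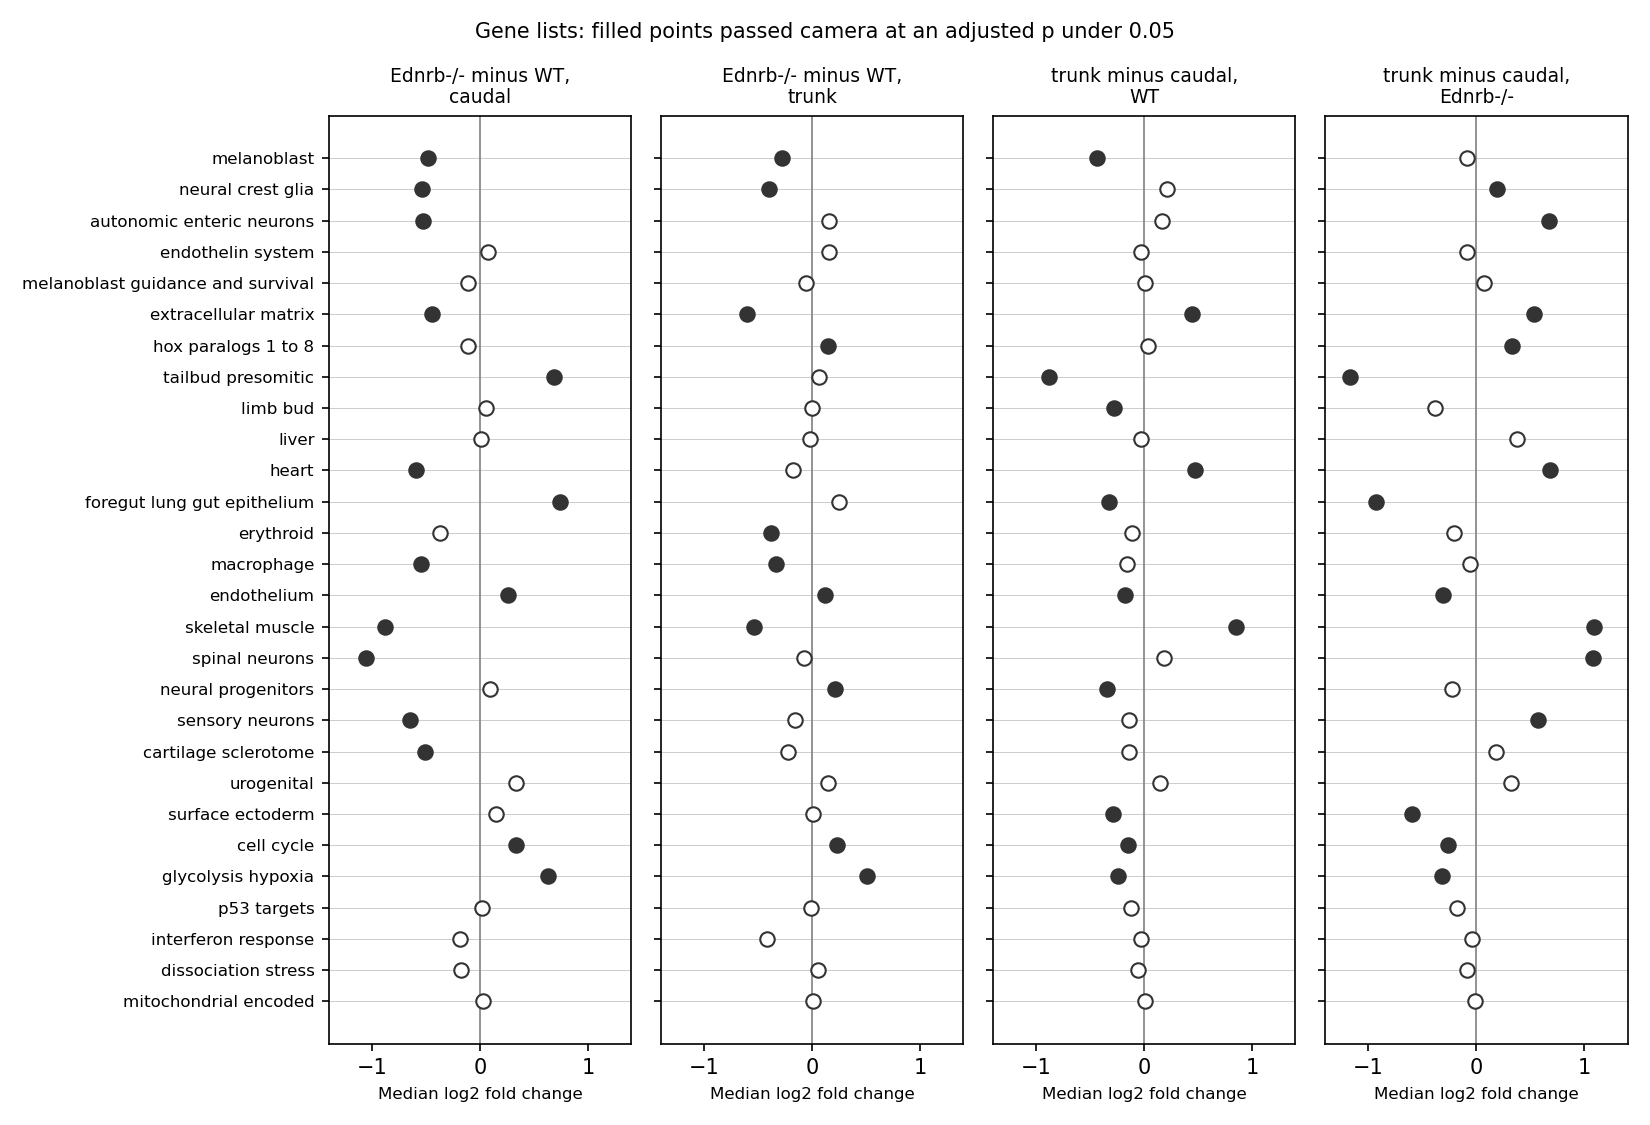
Median log2 fold change (x axes) of 28 gene lists (y axis) in the 4 comparisons, where filled points passed limma camera at an adjusted p under 0.05 and open points did not. The list of Hox paralogs 10 to 13 is left out because its medians between the regions, -4.47 in WT and -4.36 in Ednrb-/-, exceed the axis; cell cycle and glycolysis lists lie above 0 in both genotype panels and below 0 in both region panels.

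Trunk and caudal regions of WT embryos were compared to see how the regions differ when the receptor is present. Posterior Hox genes separated them most. Hoxc11 was 34 ± 6.76 FPKM in caudal and 0.145 ± 0.208 FPKM in trunk tissue (SD, n = 4; log2 -5.77 ± 0.17, limma adjusted p = 3e-12). Hoxc12 (-5.6), Hoxc13 (-5.11), Hoxd11 (-4.81), Hoxd13 (-4.81), Hoxd12 (-4.62), Hoxa11 (-4.32) and Hoxd10 (-4.08) were also lower in the trunk. All 12 Hox paralogs 10 to 13 were lower, 12 adjusted over the list alone (camera adjusted p = 5.4e-31; adjusted p = 0.0019 with an estimated correlation). Hoxc8 was higher in the trunk, at 61 ± 7.23 against 10.4 ± 1.36 FPKM (2.5 ± 0.1, adjusted p = 7.3e-11). Kctd14 (2.49), Myh8 (2.14), Kera (2.07), Ogn (1.99), Sim2 (1.89), Srd5a2 (1.84) and Zpld1 (1.8) were higher in the trunk as well.

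Melanoblast genes were lower in WT trunk than in WT caudal tissue for 5 of 8 measured, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00027; adjusted p = 0.17 with an estimated correlation). Pmel stood at log2 -1.85 ± 0.13 (limma adjusted p = 2.6e-07), Dct at -1.15 ± 0.15 (0.00012), Gpnmb at -1 ± 0.12 (4.9e-05) and Kit, the stem cell factor receptor of melanoblasts, at -0.35 ± 0.06 (0.00052). Sox10 was lower (-0.38) and Fabp7 higher (0.88). Ednrb itself did not pass (0.34 ± 0.16, adjusted p = 0.16), though it did with only the compared groups in the fit (0.022) and with voom on whole reads (0.0078). Nor did the values pass for Edn3 (0.18, 0.17), Edn1 (-0.31, 0.31) or Ednra (0.21, 0.27). Ece1 was lower in the trunk (-0.23, adjusted p = 0.039), a call lost without any 1 of the WT caudal libraries or WT trunk replicate 1 or 3, where the adjusted p ran up to 0.12, without the filter (0.077) and with a sex term (0.066). Of 37 guidance and survival genes 10 were lower and 7 higher in the trunk, 10 and 13 adjusted over the list alone, with Nrp1 at -0.43, Cxcl12 at -0.51 and Igf1 at 1.31 (adjusted p = 0.83; adjusted p = 0.88 with an estimated correlation).

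Skeletal muscle genes were higher in WT trunk for 11 of 14 and lower for 2, 11 and 3 adjusted over the list alone, such as Myog (1.12) and Actc1 (0.86) (camera adjusted p = 1.8e-06; adjusted p = 0.2 with an estimated correlation). Extracellular matrix genes were higher for 19 of 28 and lower for 4, 19 and 5 adjusted over the list alone, such as Tnc (1.79) and Dcn (1.76) (adjusted p = 3.3e-07; adjusted p = 0.25 with an estimated correlation). Heart genes were higher for 4 of 7, 5 adjusted over the list alone, such as Myh6 (0.82) and Myl4 (0.71) (adjusted p = 0.0015; adjusted p = 0.2 with an estimated correlation). Tailbud genes were lower for 10 of 18, 15 adjusted over the list alone, with T, the brachyury gene, at -1.95 and Cyp26a1, which breaks down retinoic acid, at -1.04 (adjusted p = 4.9e-08; adjusted p = 0.23 with an estimated correlation). Limb bud genes were lower for 6 of 17 and higher for 2, 7 and 2 adjusted over the list alone, with Msx1 at -0.66 (adjusted p = 0.0064; adjusted p = 0.25 with an estimated correlation). That list's call was lost without WT caudal replicate 4 (adjusted p = 0.054).

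Gut epithelium genes were lower in WT trunk for 6 of 9 and higher for 1, the same counts adjusted over the list alone, such as Shh (-0.83) and Cdh1 (-0.64) (camera adjusted p = 0.0013; adjusted p = 0.2 with an estimated correlation). Surface ectoderm genes were lower for 6 of 14, with 9 lower and 1 higher adjusted over the list alone, such as Krt8 (-0.88) and Krt19 (-0.83) (adjusted p = 0.00063; adjusted p = 0.32 with an estimated correlation). Endothelial genes were lower for 7 of 13, 9 adjusted over the list alone, such as Emcn (-0.36) and Cdh5 (-0.28) (adjusted p = 9.3e-05; adjusted p = 0.2 with an estimated correlation). Neural progenitor genes were lower for 4 of 13, 5 adjusted over the list alone, such as Dbx1 (-0.82) and Pax6 (-0.52) (adjusted p = 0.0021; adjusted p = 0.49 with an estimated correlation), a call lost with fry (0.054). Cell cycle genes were lower for 7 of 20, 13 adjusted over the list alone, such as Plk1 (-0.27) and Mki67 (-0.16) (adjusted p = 3.4e-06; adjusted p = 0.34 with an estimated correlation). Glycolysis genes were lower for 10 of 20, with 10 lower and 2 higher adjusted over the list alone, such as Ldha (-0.5) and Pfkl (-0.38) (adjusted p = 0.0012; adjusted p = 0.25 with an estimated correlation). In all, 3103 genes differed (1667 higher and 1436 lower in the trunk), of which 214 differed at least 2-fold. The count was 1912 without the 3 libraries, of all groups, with Xist and Ddx3y both at 5 FPKM or more. The call of Plk1 was also lost there (limma adjusted p = 0.053). The other 16 lists did not pass.

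The same regions were compared in Ednrb-/- embryos. Posterior Hox genes again differed most: Hoxc11 was listed at 0 in all 4 trunk libraries against 27 ± 2.42 FPKM in caudal tissue (SD, n = 4; limma adjusted p = 2.9e-12). Hoxd13 stood at log2 -5.48, Hoxd12 at -4.67, Hoxc12 at -4.59, Hoxa11 at -4.52, Hoxd11 at -4.5, Hoxd10 at -4.23 and Hoxa13 at -4.17. All 12 Hox paralogs 10 to 13 were lower in the trunk, 12 adjusted over the list alone (camera adjusted p = 3.6e-20; adjusted p = 0.013 with an estimated correlation). Dbh, an enzyme of noradrenaline synthesis, was higher in the trunk by 2.67 ± 0.3 (adjusted p = 1.2e-05), Myod1 by 2.61, Hoxc8 by 2.46, Kctd14 by 2.42, Tnnt1 by 2.4, Prph by 2.35, Casq2 by 2.33 and Slc17a6 by 2.27. Of 37 guidance and survival genes 8 were lower and 12 higher, 8 and 13 adjusted over the list alone (adjusted p = 0.35; adjusted p = 0.71 with an estimated correlation). Dkk1, a Wnt antagonist, was lower (-2.01), as was Robo2 (-1.29), and Igf1 was higher (1.31).

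The melanoblast list did not pass between the regions of Ednrb-/- embryos, with 3 of 8 members lower and 1 higher in the trunk, 3 and 2 adjusted over the list alone (median -0.09, camera adjusted p = 0.57; adjusted p = 0.76 with an estimated correlation). Pmel was lower (-0.77 ± 0.13, limma adjusted p = 0.00036), Kit lower (-0.3) and Rab27a, which tethers melanosomes, higher (0.56). Ednrb reads were higher in the trunk (0.7 ± 0.16, adjusted p = 0.0031). Ece1 was lower (-0.28, adjusted p = 0.009) and Ednra higher (0.44, 0.013), the latter a call lost without Ednrb-/- caudal replicate 2 (0.051). Edn3 (0.09, 0.48) and Edn1 (-0.34, 0.2) did not pass, and Edn1 had 0.034 without Ednrb-/- caudal replicate 1.

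In the Ednrb-/- trunk skeletal muscle genes were higher for 13 of 14, 13 adjusted over the list alone, such as Myh3 (1.86) and Actc1 (1.29) (camera adjusted p = 5.9e-12; adjusted p = 0.083 with an estimated correlation). Spinal neuron genes were higher for 13 of 17, 13 adjusted over the list alone, such as Stmn2 at 1.46 (adjusted p = 1.2e-08; adjusted p = 0.23 with an estimated correlation). Sensory neuron genes were higher for 8 of 12 and lower for 2, the same counts adjusted over the list alone, such as Ntrk3 (1.08) and Ntrk2 (0.97) (adjusted p = 0.0059; adjusted p = 0.32 with an estimated correlation). Autonomic and enteric neuron genes were higher for 11 of 16, with 11 higher and 1 lower adjusted over the list alone, such as Chgb (1.61) and Chga (1.27) (adjusted p = 0.00017; adjusted p = 0.23 with an estimated correlation). Neural crest glia genes were higher for 7 of 15 and lower for 2, the same counts adjusted over the list alone, such as Fabp7 (1.36) and Erbb3 (0.54) (adjusted p = 0.015; adjusted p = 0.3 with an estimated correlation). Hox paralogs 1 to 8 were higher for 15 of 23 and lower for 4, the same counts adjusted over the list alone, such as Hoxc6 (1.87) and Hoxa7 (1.26) (adjusted p = 2.6e-05; adjusted p = 0.32 with an estimated correlation). Matrix genes were higher for 17 of 28 and lower for 6, 18 and 6 adjusted over the list alone, such as Lum (1.9) and Dcn (1.69) (adjusted p = 0.00017; adjusted p = 0.37 with an estimated correlation). Heart genes were higher for 5 of 7, 5 adjusted over the list alone, such as Myh7 at 1.56 (adjusted p = 0.00017; adjusted p = 0.13 with an estimated correlation).

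Lower in the Ednrb-/- trunk were tailbud genes, 16 of 18 and 16 adjusted over the list alone, such as Cdx4 (-2.48) and Nkx1-2 (-1.2) (camera adjusted p = 7.7e-09; adjusted p = 0.23 with an estimated correlation). Gut epithelium genes were lower for 8 of 9, 8 adjusted over the list alone, such as Shh (-1.46) and Cdh1 (-0.93) (adjusted p = 6.4e-06; adjusted p = 0.083 with an estimated correlation). Surface ectoderm genes were lower for 10 of 14 and higher for 1, the same counts adjusted over the list alone, such as Krt8 (-1.4) and Krt19 (-1.3) (adjusted p = 2.6e-05; adjusted p = 0.23 with an estimated correlation). Endothelial genes were lower for 11 of 13, 12 adjusted over the list alone, such as Cdh5 (-0.38) and Kdr (-0.31) (adjusted p = 1.5e-06; adjusted p = 0.13 with an estimated correlation). Cell cycle genes were lower for 17 of 20, 17 adjusted over the list alone, such as Mcm2 (-0.4) and Mcm3 (-0.39) (adjusted p = 1.1e-07; adjusted p = 0.29 with an estimated correlation). Glycolysis genes were lower for 12 of 20 and higher for 3, the same counts adjusted over the list alone, such as Slc2a1 (-0.74) and Pfkl (-0.57) (adjusted p = 0.0033; adjusted p = 0.3 with an estimated correlation). In all, 6234 genes differed (2982 higher and 3252 lower in the trunk), of which 465 differed at least 2-fold. After rescaling to TPM the split was 3936 and 1945. The other 14 lists did not pass, among them neural progenitors, with 5 of 13 lower and 2 higher, 6 and 2 adjusted over the list alone (adjusted p = 0.14; adjusted p = 0.74 with an estimated correlation). The regional differences of the genotypes, which share no library, correlated across genes (Pearson r = 0.63, Spearman rho = 0.46). They shared 1113 higher genes, against 289 for independent lists, and 833 lower genes, against 271, with 101 opposite. The shared estimate of spread may make these counts for independent lists too low as well.

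Whether the genotype effect differed between the regions was tested as an interaction, the trunk effect minus the caudal effect. Among the large positive values were those of Rgs4 (1.98 ± 0.35, limma adjusted p = 0.007), Kcnmb2 (1.89), Myf6 (1.77), Grm2 (1.76), Robo3 (1.71), Dbh (1.7), Car3 (1.61 ± 0.12, adjusted p = 9.4e-06) and Myf5 (1.57). On the negative side Pitx1 stood at -2.19 ± 0.53 (adjusted p = 0.026), with 5.14 ± 3.8 FPKM in WT and 10.6 ± 1.47 FPKM in Ednrb-/- caudal tissue, against 5.09 ± 1.77 and 2.28 ± 0.54 FPKM in the trunk (SD, n = 4). Tbx4 stood at -2.15 ± 0.49 (0.019), Kera at -1.47, Snord43 at -1.44, Cdx4 at -1.44, Ifitm1 at -1.39, Ripply1 at -1.39 and Wfikkn1 at -1.36. The call of Pitx1 was lost without Ednrb-/- caudal replicate 4, Ednrb-/- trunk replicate 3, WT caudal replicate 1 or WT trunk replicate 1 (adjusted p up to 0.057), and that of Wfikkn1 without Ednrb-/- caudal replicate 4 or Ednrb-/- trunk replicate 1 (up to 0.051). That of Dbh was lost without Ednrb-/- caudal replicates 2 or 4, Ednrb-/- trunk replicates 1 or 3, WT caudal replicates 1 or 4 or WT trunk replicate 1 (up to 0.059). The call of Cdx4 held only without Ednrb-/- caudal replicate 3 or WT caudal replicates 2, 3 or 4 (otherwise up to 0.083). That of Ifitm1 held only without those libraries or WT trunk replicate 3 (otherwise up to 0.096), and that of Snord43 only without Ednrb-/- caudal replicate 1, Ednrb-/- trunk replicate 3, WT caudal replicates 2 or 3 or WT trunk replicate 4 (otherwise up to 0.08). Without the filter the calls of Pitx1 (0.063), Wfikkn1 (0.056), Dbh (0.067), Cdx4 (0.094), Ifitm1 (0.11) and Snord43 (0.096) were lost, and with voom those of Tbx4 (0.13), Kera (0.79), Cdx4 (0.24) and Snord43 (0.069). A pseudocount of 0.1 ended those of Kera (0.053) and Cdx4 (0.076), quantile normalization that of Ifitm1 (0.064) and array weights that of Snord43 (0.052).

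Melanoblast genes had a positive interaction for 3 of 8, 3 adjusted over the list alone: Pmel (1.07 ± 0.18, limma adjusted p = 0.0055), Dct (1.04 ± 0.22, 0.013) and Gpnmb (0.92 ± 0.17, 0.0082). The list passed (camera adjusted p = 0.00046; adjusted p = 0.16 with an estimated correlation). These genes were near the pseudocount in the trunk, which shrinks their trunk fold. With a pseudocount of 0.1 Pmel stood at 0.78 (adjusted p = 0.13) and Gpnmb at 1.51 (0.06), and with voom on whole reads at 0.43 (0.59) and 1.25 (0.34). Ednrb (0.36, 0.35), Edn3 (-0.1, 0.7), Edn1 (-0.03, 0.96), Ece1 (-0.04, 0.86) and Ednra (0.22, 0.49) did not pass.

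Spinal neuron genes had a positive interaction for 12 of 17, 14 adjusted over the list alone, such as Nefm (1.49) and Nefl (1.29) (camera adjusted p = 1.6e-10; adjusted p = 0.19 with an estimated correlation). So did 7 of 12 sensory neuron genes, 8 adjusted over the list alone, such as Ntrk3 at 0.8 (adjusted p = 3.8e-07; adjusted p = 0.16 with an estimated correlation). Skeletal muscle genes did for 8 of 14, 10 adjusted over the list alone, including Myf5 and Myf6 (adjusted p = 8.2e-08; adjusted p = 0.16 with an estimated correlation). Hox paralogs 1 to 8 did for 7 of 23, 13 adjusted over the list alone, such as Hoxa4 (0.74) and Hoxd3 (0.61) (adjusted p = 3.8e-07; adjusted p = 0.35 with an estimated correlation). Autonomic and enteric neuron genes did for 6 of 16, 9 adjusted over the list alone, such as Chrna3 (0.99) and Chgb (0.74) (adjusted p = 0.00055; adjusted p = 0.35 with an estimated correlation). The call of Chgb was lost without Ednrb-/- trunk replicate 1, WT caudal replicate 1 or WT trunk replicate 1 (up to 0.053), and without the filter (0.056). Cartilage and sclerotome genes did for 3 of 13, with 8 positive and 1 negative adjusted over the list alone, such as Pax1 (0.86) and Pax9 (0.71) (adjusted p = 0.00055; adjusted p = 0.35 with an estimated correlation).

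Gut epithelium genes had a negative interaction for 4 of 9, 4 adjusted over the list alone, such as Foxa1 (-0.93) and Epcam (-0.6) (camera adjusted p = 0.00033; adjusted p = 0.16 with an estimated correlation). Tailbud genes did for 2 of 18, 3 adjusted over the list alone, such as Nkx1-2 at -1.03 (adjusted p = 0.018; adjusted p = 0.69 with an estimated correlation). Endothelial genes did for 2 of 13, 2 adjusted over the list alone, Cldn5 (-0.39) and Egfl7 (-0.29) (adjusted p = 0.023; adjusted p = 0.52 with an estimated correlation). Surface ectoderm genes did for 1 of 14, Krt18 (-0.7), and 6 adjusted over the list alone (adjusted p = 0.0097; adjusted p = 0.52 with an estimated correlation). The cell cycle list passed with 0 of 20 members past the threshold, 0 adjusted over the list alone (adjusted p = 0.018; adjusted p = 0.74 with an estimated correlation). The tailbud, endothelial, surface ectoderm and cell cycle lists did not pass with fry (adjusted p = 0.24, 0.088, 0.12 and 0.35). The tailbud call was also lost without WT caudal replicate 4 (0.15) or WT trunk replicate 3 (0.054), and the endothelial call without WT caudal replicate 3 (0.08) or WT trunk replicate 2 (0.089). The cell cycle call was lost without Ednrb-/- caudal replicate 2 (0.094), WT caudal replicate 4 (0.12) or WT trunk replicate 1 (0.13). Cldn5 kept its call only without Ednrb-/- caudal replicate 1, Ednrb-/- trunk replicates 2 or 4 or WT caudal replicate 2 (otherwise up to 0.087). Egfl7 kept it only without Ednrb-/- caudal replicates 1 or 3, Ednrb-/- trunk replicate 2, WT caudal replicate 2 or WT trunk replicate 3 (up to 0.1), and Krt18 only without Ednrb-/- caudal replicate 3 or WT trunk replicates 3 or 4 (up to 0.091). Other settings ended these calls too: no filter (0.096 for Cldn5, 0.094 for Egfl7, 0.1 for Krt18), TPM (0.06, 0.1 and 0.061) and array weights (0.061, 0.051 and 0.072). Quantile normalization ended those of Egfl7 (0.074) and Krt18 (0.087), voom that of Egfl7 (0.068), and a pseudocount of 0.1 that of Krt18 (0.055). Of 37 guidance and survival genes 2 were negative, Robo2 (-0.98) and Wnt5a (-0.79), and 4 positive, such as Cxcl12 (0.54), 3 and 7 adjusted over the list alone (adjusted p = 0.15; adjusted p = 0.54 with an estimated correlation). In all, 1163 genes had an interaction (650 positive and 513 negative), of which 121 were at least 2-fold. The split was 1130 and 299 after rescaling to TPM and 1187 and 447 with voom, and the count was 571 without the filter. It was 673 and 585 without Ednrb-/- caudal replicates 2 and 4, 606 and 672 without Ednrb-/- trunk replicates 1 and 3, 670 without WT caudal replicate 1 and 648 without WT trunk replicate 1. The other 17 lists did not pass.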

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

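The tests of an equal fall of melanoblast or Slc24a5 and glia RNA were chosen after the results were seen. So were the interval of the Hox median, the bound on the melanoblast median and the interaction regroupings with effects removed. The sex term was added after the data were examined. The other tests of causes here, and their lists of stage, melanoblast and glia genes, were made for patterns seen in the main results.

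The genotype difference was broad in both regions. Only the real split of the 8 libraries, 1 of 35, gave as many genes in the caudal (7164, highest other split 1) and trunk (4321, highest other 1) genotype comparisons. The same held for the region comparisons in WT (3103, highest other 2) and in Ednrb-/- (6234, highest other 1). This argues against a chance split of the libraries, though 1 of 35 is the smallest share the test can give. It cannot set apart litter or strain differences that follow the groups.

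Genes within 10 Mb of Ednrb held 0.237% of caudal and 0.324% of trunk calls. With only 35 tested genes there a small share was fixed in advance, and these genes cannot themselves make up the breadth. Of them 48.6% (all genes 41.6%) and 40% (all genes 25.1%) were called. Whether changes around the locus act on genes elsewhere was not tested and stays open. The tables argue against sex as the whole cause, since with a sex term the counts were 0.972 and 0.935 times as high (6762 and 3904 calls shared), and against a shift in scaling as the whole cause, since with quantile normalization they were 0.923 and 1.06 times as high (5535 and 3915 shared). An earlier stage of the Ednrb-/- embryos may contribute: genes that fall with stage (such as Lin28b and Mycn) exceeded genes that rise with stage (such as Nfib and Meg3) by 0.64 in caudal and 0.73 in trunk tissue, which 2 and 0 of 10000 expression-matched random lists reached. The random lists were drawn gene by gene and do not keep genes that move together. If the stage genes do so, these shares overstate the evidence. The stage lists also differed between the regions of WT embryos (trunk minus caudal -1.16), and stage was not separated from tissue make-up. Loss of Ednrb itself stays open, as do strain background and litter, which are not given in the sources used here.

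In the Ednrb-/- caudal region 7 of 18 tailbud genes rose (camera adjusted p = 0.0042; adjusted p = 0.49 with an estimated correlation), and Tbx4 rose by 2.03. Caudal pieces taken farther back were tested with the 12 Hox paralogs 10 to 13, whose median was -0.27 (95% interval of the median -0.38 to 0.13). This lay below 0.25 times the tailbud median of 0.68 (0.17), which argues against such pieces as the whole cause. How far such a cut raises these genes within caudal tissue was not measured, and an earlier stage may move them too. The interval treats the 12 genes as independent, though their estimated correlation was 0.312. Single members moved both ways, from -1.02 to 0.52. An earlier stage stays a candidate explanation, with the caudal difference of 0.64 above, and a local effect of the genotype was not tested.

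Melanoblast genes were lower in Ednrb-/- embryos, and so were glia genes. A glia fall as large as the melanoblast fall had been set beforehand as the sign of a general deficit or delay of neural crest derivatives. That criterion was met in caudal tissue, where the glia median (-0.7) was 2.12 times the melanoblast median (-0.33). But with 7 of 10 melanoblast genes below the filter, even full loss of the melanoblast genes gives only -0.43. This bound was added after the values were seen. The criterion thus could not decide, and the question stays open. In summed FPKM the melanoblast genes fell by 1.8 on the log2 scale and the glia genes by 0.66, a difference of -1.14 (exact permutation p = 0.029, the smallest possible), which argues against an equal fall for Pmel and Dct, the bulk of the sum (5.24 of 8 FPKM in WT; difference from glia -2.05, exact permutation p = 0.029). The 7 genes below the filter went from 0.841 to 0.216 FPKM in sum. Their difference from glia was -1.36 (exact permutation p = 0.029), at low values. Slc24a5 went from 1.92 to 1.26 FPKM, a difference from glia of 0.06 (exact permutation p = 0.66), so an equal fall of Slc24a5 and crest glia RNA was not excluded. In the trunk the difference of the sums was -0.22 (exact permutation p = 0.057). By part it was -1.29 for Pmel and Dct (exact permutation p = 0.029), 0.21 for Slc24a5 (0.17) and -0.48 for the genes below the filter (0.26). Slc24a5 held 1.89 of the 3.37 FPKM of the WT trunk sum.

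The genotype effect differed between the regions for 1163 genes. Of 100 drawn splits of the libraries within regions, 2 gave as many, the real one included (highest other 1730), but these also move the genotype effect shared by the regions and so decide nothing. In chance splits after the genotype and region effects were removed from each gene, 1 of 100, the real one, gave as many (1163, highest other 444). This argues against chance, though 1 of 100 is the smallest share these splits can give and the count moved with the processing.

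Among genes named for the genotype comparisons, those with an interaction of the trunk minus the caudal effect were positive for Slc17a6 (1.54), Vstm2l (1.57), Robo3 (1.71), Myod1 (1.07), Pmel (1.07), Gpnmb (0.92), Dct (1.04), Erbb3 (0.29), Chgb (0.74) and Spon1 (0.49). They were also positive for Actc1 (0.44), Myh3 (1.03), Stmn2 (1.11), Ntrk3 (0.8), Pax1 (0.86), Hoxc12 (1.02), Myh7 (1.19), Hmx1 (1.45), Atoh1 (1.56), Myf6 (1.77), Cxcl12 (0.54), Hoxd1 (0.53) and Myf5 (1.57). They were negative for Tbx4 (-2.15), Snord43 (-1.44), Olig2 (-1.14), Cldn6 (-0.76), Epcam (-0.6), Egfl7 (-0.29), Hoxd13 (-0.67), Cdx4 (-1.44), Nkx1-2 (-1.03), Ogn (-0.92), Npy (-0.92) and Robo2 (-0.98). Pmel, Dct and Gpnmb were near the pseudocount in the trunk, which shrinks their trunk fold. With voom Pmel stood at 0.43 (adjusted p = 0.59) and Gpnmb at 1.25 (0.34). Hoxc12 and Hoxd13 were far lower in the trunk of both genotypes, so their interactions come largely from caudal tissue.

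The lists whose effect differed had median interactions of 0.28 for melanoblast, 0.31 for autonomic and enteric neuron, 0.32 for Hox paralogs 1 to 8, 0.46 for skeletal muscle, 0.79 for spinal neuron, 0.65 for sensory neuron and 0.26 for cartilage genes. Medians were -0.57 for tailbud, -0.49 for gut epithelium, -0.11 for endothelial, -0.22 for surface ectoderm and -0.13 for cell cycle genes. With an estimated correlation none of these 12 list calls held. The melanoblast list includes genes near the pseudocount in the trunk, where folds are shrunk.

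Libraries far from the other 3 of their group were sought in 112 groups of 4 values (22 genes and 6 library measures), and 9 were found, where chance gives about 1 in 20. Tbx4 stood at 0.91 FPKM in WT trunk replicate 1. Mid1-ps1 stood at 2.72 FPKM in Ednrb-/- trunk replicate 2 and 5.78 FPKM in Ednrb-/- caudal replicate 2. Gpnmb stood at 0.12 FPKM in Ednrb-/- caudal replicate 3. Mitf stood at 0.885 FPKM in WT trunk replicate 3 and 0.607 FPKM in Ednrb-/- caudal replicate 2. Cdx2 stood at 0.0438 FPKM in Ednrb-/- trunk replicate 4, where the others were listed at 0. WT trunk replicate 4 had 43400000 reads in listed genes. Hemoglobin genes took 0.256% of reads in Ednrb-/- trunk replicate 1.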

How the results depend on the processing

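Alternatives chosen after the data were examined were the sex term, the sum of listed reads as the total, and the runs without X, Y and MT genes or without 3 libraries. The cause of each change below was not tested unless the setting itself gives it. With a 2-fold minimum, which asks for more, the counts were 421 and 187 for the caudal and trunk genotype comparisons, 214 and 465 for the regions in WT and Ednrb-/-, and 121 for the interaction. Without the filter, which tested 37417 genes, the interaction count was 571. Without the 3 libraries with Xist and Ddx3y both at 5 FPKM or more the WT region count was 1912. The other counts were 6554, 3596, 5098 and 1021. That run ended 13 gene calls, with adjusted p from 0.05 to 0.11: Dct, Gpnmb and Mir7655 (trunk genotype), Ece1 and Plk1 (WT regions), Ednra (Ednrb-/- regions), and Cdx4, Cldn5, Dbh, Egfl7, Ifitm1, Krt18 and Pitx1 (interaction). The sex term ended those of Ece1 (0.066) and, in the interaction, Cdx4 (0.052), Ifitm1 (0.057) and Krt18 (0.057), and the sum of listed reads those of Egfl7 (0.071) and Krt18 (0.056). Leaving out 1 library moved the interaction count between 585 and 1488; it was 585 without Ednrb-/- caudal replicate 4, 673 without replicate 2, 606 and 672 without Ednrb-/- trunk replicates 1 and 3, 670 without WT caudal replicate 1 and 648 without WT trunk replicate 1. The other counts stayed within 1.5 times: 6012 to 7217 (caudal), 3355 to 4511 (trunk), 2153 to 3242 (WT regions) and 4875 to 6324 (Ednrb-/- regions).

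With replicate number as a replicate block the counts were 5638, 3378, 1963, 5565 and 1023. In that run 11 gene calls and 2 list calls were lost, and 1 gene call was gained. Lists lower in the WT trunk went from 10 to 11, and lists higher in the Ednrb-/- trunk from 8 to 9. In the trunk genotype comparison the lost calls included Mitf (limma adjusted p = 0.066), Gpnmb (0.12), Dct (0.081) and the melanoblast list (camera adjusted p = 0.078). The numbers did not pair the samples: same-number correlations ran from -0.142 to 0.245, and 4 of 16 comparisons were highest for their own number.

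With an estimated inter-gene correlation 2 of 66 list calls held. With fry 60 of the 66 held, and calls were also gained. Fry called 12 lists as lower against 10 in the caudal and 7 against 6 in the trunk genotype comparison. It called 8 as lower against 7 in the Ednrb-/- trunk. In the interaction it called 8 positive and 1 negative, against 7 and 5. Of 240 called gene results, 17 lost their call without at least 1 library, as did 8 of the 66 list results. Another scaling moved the median of all genes by at most 0.087. Median-of-ratios scaling and a pseudocount of 1 changed none of the 255 gene results, and the 2-fold minimum ended 100 of the 240 calls. Results that turned sign were all uncalled. Ednra in the trunk genotype comparison stood at -0.003 with voom and -0.003 with listed reads (left-out libraries -0.005 to 0.103). The Edn1 interaction stood at 0.008 with a pseudocount of 0.1, 0.031 with TPM, 0.052 with array weights and 0.087 with voom (left-out -0.214 to 0.121). The Ece1 interaction stood at 0.033 with TPM (left-out -0.118 to 0.003). Counts of low genes past the exact permutation test were 0 at both pseudocounts after adjustment and 10 at an unadjusted p under 0.05 (4, 4, 2 and 0). The smallest possible p made the adjusted threshold hard to pass.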

Other observations

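The comparison of totals was made after the data were examined. The lists of stage genes were made for patterns seen in the main results. No other test here was chosen after its result was seen.

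Of 7 tested genes chosen because they fall with embryonic stage, 5 rose in both regions, and of 9 that rise with stage, 3 fell in both. Lin28b, a partner of Lin28a in blocking let-7, rose by 1 in caudal and 0.89 in trunk tissue of Ednrb-/- embryos (limma adjusted p = 2.7e-05 and 0.00019). Mycn rose by 0.54 and 0.46, Dnmt3b, a DNA methyltransferase, by 0.44 and 0.54, Igf2bp1 by 0.34 and 0.61, and Hmga2 by 0.36 and 0.43. Nfib, a factor of later differentiation, fell by 0.86 and 0.64, Cdkn1c, an imprinted inhibitor of cell division, by 0.7 and 0.36, and Meg3 by 0.27 and 0.36. Zbtb20 (-0.6) and Mir99ahg (-0.55) passed in caudal tissue alone, and Rian (-0.28), H19 (-0.27) and Mirg (-0.26) in the trunk alone. Dlk1, another imprinted gene on the list of later genes, went the other way in caudal tissue and rose by 0.89 (adjusted p = 5.8e-05), while its trunk value was 0.03 (0.89). L1td1 and Crabp1 passed in neither region.

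Sex-linked RNA differed between libraries. Xist stood at 135.4 FPKM or above and Ddx3y at 0.977 FPKM or below in WT trunk replicates 1 and 4, WT caudal replicate 1 and Ednrb-/- trunk replicate 2. No Ednrb-/- caudal library was of this kind. Some Y-linked RNA was present even so: Ddx3y and Eif2s3y stood at 0.977 and 1.406 FPKM in Ednrb-/- trunk replicate 2. They stood at 0.903 and 0.932 FPKM in WT caudal replicate 1, against 0.05 and 0 in WT trunk replicate 1. WT caudal replicate 2 (Xist 9.18 FPKM), Ednrb-/- trunk replicate 3 (9.92 FPKM) and Ednrb-/- caudal replicate 3 (5.72 FPKM) held Xist together with high Y-linked RNA, with Ddx3y between 17.32 and 17.83 FPKM. The run without 3 libraries left out only these last, not those with little Y-linked RNA.

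The total behind the deposited FPKM, as a share of listed reads, also followed the groups, from 0.977 ± 0.0217 (SD, n = 4) in Ednrb-/- caudal to 1.03 ± 0.00711 in WT trunk libraries.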
